A study of Mus musculus with 32 samples.

How the data were processed

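RNA was sequenced from brown adipose tissue (BAT), heart, liver and skeletal muscle of male C57BL/6J mice. Per the labels, each tissue was taken from wild-type mice (WT) and from mice of a Smim30 knockout line, whose libraries are labelled Mut. The 32 libraries fall into 8 groups of 4, and each library's group and replicate number were taken from its title. Per the labels, total RNA was extracted with a magnetic bead kit and made into strand-specific Illumina libraries.

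The deposited values are TPM (abundances scaled to a fixed sum per library) per transcript, made by the authors with Salmon, a tool that assigns reads to transcripts. Salmon's version, the transcriptome release and the genome build are not given in the sources used here. The TPM of each library summed to between 999999.4 and 1000000.3. TPM keeps no read totals, so the depth of each library is unknown, and no counting interval or limit of detection is given. Precision was read from the spread between replicates.

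The table holds 147493 transcript identifiers. Identifiers were matched, with version numbers ignored, to GENCODE release M21 on the mouse build GRCm38, which matched 136081 (92.26%). TPM values were summed over the transcripts of each gene, which gave 51510 genes. The 11412 unmatched transcripts held 0.451% to 0.896% of the TPM of a library and were left out of the gene comparisons. The annotation does not use the symbol Smim30. The gene was taken to be 2610001J05Rik (ENSMUSG00000052419), whose transcripts encode the SMIM30 small protein, and it is called Smim30 throughout.

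Each tissue was fitted on its own with limma 3.58.1 in R 4.3.3 (linear models with a mean-variance trend), on log2(TPM + 1). Genes with a mean of at least 1 TPM over the 8 libraries of the tissue were tested for Mut minus WT. All tests are two-sided unless named otherwise. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The pseudocount of 1 makes fold changes of genes at low TPM smaller than the ratio of their means. Smim30 was also tested by an exact permutation test of the log2 values over all 70 assignments of 8 libraries, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over the 4 tissues. The p-values of limma and of the permutation test measure the spread between these libraries. Those of the list tests with a preset correlation and of the overlap tests, described below, rest on comparisons between genes instead. The submitters describe 4 individual mice per tissue, and whether a replicate number marks the same mouse in several tissues is not stated.

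There were 63 gene lists (pathways, protein complexes and cell type markers), fixed before the data were examined together with the tests, the thresholds, the alternative settings and the rule for naming genes. Of these, 1 served for checks of the labels, and up to 62 were open to a set test. Lists with at least 5 measured members were tested with limma's camera, which compares a list's genes with all other genes of the tissue. An inter-gene correlation of 0.01 was preset, and the test was repeated with a correlation estimated from the data. Members of each list were counted as changed over all genes tested and as adjusted over the list alone. Some genes taken by the naming rule are not reported here.

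Differences between tissues were tested in 1 limma model over all 32 libraries, on genes with a mean of at least 1 TPM in every tissue. It gave an F test of the tissue by genotype interaction, the differences between pairs of tissues, and the mean of the 4 effects, with the libraries taken as independent. The overlap of gene calls between tissues was tested with Fisher's exact test, one-sided. Named genes are Smim30, up to 10 rises and 10 falls per tissue with the largest fold changes among called genes whose groups do not overlap, up to 4 members of each called list by smallest p, and genes over tissues (shared calls, and the 5 smallest interaction p). Where fewer than 10 genes passed in a tissue, the 10 with the smallest p were added. Provisional gene names were counted only. Genes outside this rule are named as chosen after their values were seen.

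The procedure was tested on simulated data drawn from each tissue's gene means and spread, with 200 altered genes per tissue. Each gene was drawn on its own, so the simulation does not show how the tests behave when genes vary together. The alternatives tried were another pseudocount (0.1), no filter and a filter at 5 TPM, median-ratio scaling, rescaling without mitochondrial and the 10 most abundant genes, limma without the trend, limma array weights, the replicate number as a block, 1 fit over all libraries, an adjusted p under 0.1, genes above the minimum in any tissue, an estimated inter-gene correlation, and leaving out each library in turn. Alternatives with a score of atrial or slow fibre genes as a covariate, and without 2 WT libraries of BAT, were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.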

Results

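The gene expression of 4 tissues was measured by RNA sequencing in male mice, with 4 WT and 4 Mut libraries for each of BAT, heart, liver and skeletal muscle. Between 11480 and 12431 genes reached 1 TPM in a library. Ucp1, the uncoupling protein of brown fat, averaged 3066 ± 520.1 TPM in WT BAT (SD, n = 4) and 48.4 to 62.7 TPM in the WT libraries of the other tissues. Myh6 (heart), Alb (liver) and Acta1 (skeletal muscle) were likewise highest in the tissue named by the labels. Xist stayed at or under 0.0594 TPM and Ddx3y at or above 14.8 TPM in every library, as in male tissue. Mitochondrially encoded genes took 36.7% ± 1.11 of the TPM in WT BAT and 34.9% ± 2.84 in Mut BAT (SD, n = 4). In heart they took 42.0% ± 1.16 in WT and 45.9% ± 5.92 in Mut, with 54.5% in Mut library 2. In liver these shares were 11.7% ± 1.81 and 12.5% ± 1.45, and in muscle 27.2% ± 2.02 and 26.3% ± 3.57.

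The first comparison asked whether Smim30 RNA was lower in the libraries labelled Mut. Smim30 encodes a small integral membrane protein and lies on chromosome 6 from 13867735 to 13871518 (GRCm38). Its RNA was present in all libraries labelled Mut, at 17.3 TPM or more. In heart it averaged 34.6 ± 2.08 TPM in WT and 23.6 ± 4.21 TPM in Mut (SD, n = 4), a change of -31.8%. In muscle it averaged 34.3 ± 1.20 TPM in WT and 25.9 ± 1.20 TPM in Mut, a change of -24.5%. In both tissues the 4 Mut libraries lay below the 4 WT libraries. In liver it averaged 23.2 ± 3.55 TPM in WT and 21.1 ± 3.38 TPM in Mut, and in BAT 28.7 ± 4.25 TPM in WT and 29.5 ± 2.43 TPM in Mut. The exact permutation p was 0.0286 in heart and in muscle, the smallest the design allows, and 0.0571 after adjustment over the 4 tissues. It was 0.429 in liver and 0.686 in BAT. Over all genes, limma gave adjusted p = 0.320 in heart, 0.224 in muscle, 0.569 in liver and 0.852 in BAT. With 1 fit over all libraries the heart difference passed (log2 fold change -0.55, adjusted p = 0.0181), and also with array weights (-0.50, adjusted p = 0.0374). The adjusted p in heart ranged from 0.0181 to 0.977 over the alternatives. Averaged over tissues, with the libraries taken as independent, Smim30 fell in the limma model (log2 fold change -0.26, adjusted p = 0.0156). This average includes BAT, where Smim30 was not lower. Most of its TPM lay on the transcript ENSMUST00000155856.2 in every library. The RNA level therefore does not by itself check the genotype labels, since an allele can remove a protein and leave RNA.

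**Figure D1:**
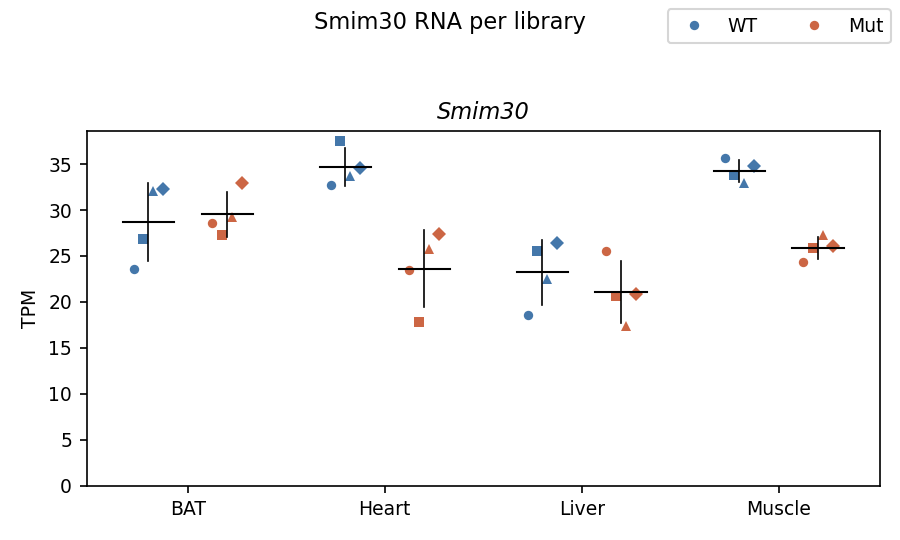
Smim30 RNA in TPM (vertical axis) per library in the 4 tissues, WT in blue and Mut in orange, with a marker shape per replicate number, the group mean as a horizontal line and the SD as a bar (n = 4). The Mut libraries lie below the WT libraries in heart (17.8 to 27.4 against 32.7 to 37.6 TPM) and muscle (24.3 to 27.3 against 32.9 to 35.7 TPM) and overlap with them in BAT and liver.

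Each tissue was then compared between genotypes over all genes. In heart the largest falls were of Myl7, Myl4, Sln and Nppa, genes known from the atria, although no list of atrial genes was fixed before the data were examined. Myl7, the atrial regulatory light chain of myosin (chromosome 11, 5896637 to 5898782), fell from 412 ± 236 TPM in WT to 7.44 ± 8.81 TPM in Mut (SD, n = 4; log2 fold change -5.78, SE 0.64, adjusted p = 0.00401). Myl4, the atrial essential light chain, fell from 318 ± 190 to 6.53 ± 7.03 TPM (log2 fold change -5.44). Sln, which encodes the calcium pump regulator sarcolipin, fell from 76.0 ± 44.4 to 1.08 ± 1.08 TPM (log2 fold change -5.04), and Nppa, the atrial natriuretic peptide precursor, from 1060.4 ± 808 to 43.9 ± 22.0 TPM (log2 fold change -4.21, adjusted p = 0.0496). Mybphl (-3.66), Fgf12 (-2.62), Tmem163 (-2.06), Gng2 (-1.46) and Ptgfr (-1.18) also fell, as did Ramp1. Ide, the insulin degrading enzyme, fell from 35.7 ± 5.34 to 17.3 ± 0.474 TPM (log2 fold change -0.99, adjusted p = 0.00475). The gene Rab4a, a small GTPase of endosome recycling, was the 1 gene that rose (3.13 ± 0.538 to 5.90 ± 0.574 TPM, log2 fold change 0.74, adjusted p = 0.0397). With a score of atrial markers as a covariate, added after the data were seen, no heart gene passed, and the log2 fold change of Myl7 went to -3.73, that of Nppa to -2.12 and that of Tmem163 to -0.96. Myl7 read 2.64 to 3.76 TPM in 3 of the Mut heart libraries, near its level in the libraries of BAT, liver and muscle (1.90 to 6.59 TPM), so its fold change depends on that floor.

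**Figure D2:**
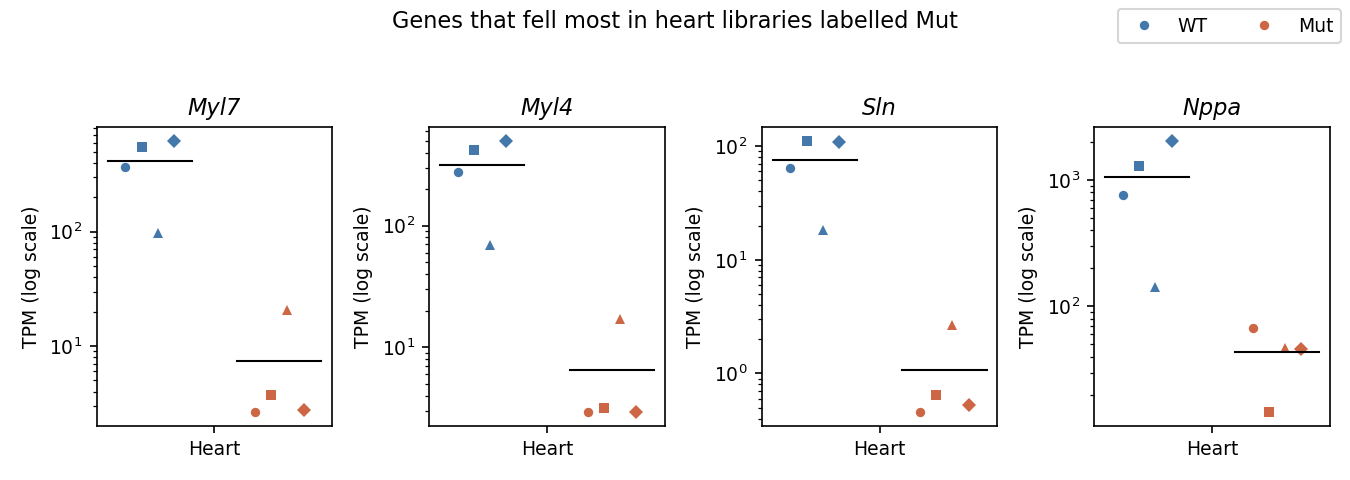
TPM on a log axis of Myl7, Myl4, Sln and Nppa per heart library, WT in blue and Mut in orange, with a marker shape per replicate number and the group mean as a line (n = 4). The Mut means are 7.44, 6.53, 1.08 and 43.9 TPM against WT means of 412, 318, 76.0 and 1060.4 TPM.

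In all, 18 of 12019 genes changed in heart, 1 up and 17 down, of which 5 have provisional names. At an unadjusted p under 0.05 there were 69 higher and 1330 lower genes, where independent genes would give 601 by chance, but 3 of the 35 splits of the 8 libraries into 4 and 4, the real one included, gave as many (highest other 2696). The 4 Mut libraries lay entirely above or below the 4 WT libraries for 905 genes (7.53%, where chance gives 2.86%). The median log2 fold change over all genes was -0.11 in heart, 0.09 in BAT, 0.10 in liver and 0.05 in muscle, and 0.00 in heart, 0.01 in BAT, 0.02 in liver and 0.01 in muscle with median-ratio scaling. Rescaling without mitochondrial and the 10 most abundant genes gave 2 rises and 10 falls in heart, and median-ratio scaling 11 genes. No gene passed with no filter on low values, where every gene is tested. Leaving out 1 library gave 7 genes (without WT 4), 8 (without WT 1, WT 2 or Mut 4), 9 (without Mut 2), 12 (without Mut 1), 16 (without Mut 3) or 20 (without WT 3), and Nppa passed only when WT 3 was the library left out. Rab4a passed only when WT 4 or Mut 3 was left out, and its log2 fold change stayed between 0.67 and 0.81. Of the 13 named heart genes that passed, 7 lost their call without WT 1, WT 2, Mut 1, Mut 2 or Mut 4, 6 without WT 4, 3 without WT 3 and 2 without Mut 3. Over all alternatives tested the call held in 4 of 17 for Ptgfr, 5 of 17 for Ramp1, 6 of 17 for Tmem163, 7 of 18 for Mybphl and 8 of 17 for Fgf12, and in 16 of 18 for Myl7, Myl4, Sln and Ide.

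Transcripts of the translation and respiration machinery were lower in the Mut heart libraries as groups. All 46 measured cytosolic ribosomal protein genes were lower (median log2 fold change -0.45, camera adjusted p = 3.87e-14; adjusted p = 0.980 with an estimated correlation), as Rpl13 (386 ± 22.9 to 270.5 ± 64.1 TPM). None passed over all genes, and 41 fell when adjusted over the list alone. The nuclear genes of respiratory complex I were lower in 34 of 36 (median -0.32, adjusted p = 3.71e-05), those of complex IV in 13 of 13 (-0.37, adjusted p = 0.000192), those of complex V in 15 of 15 (-0.32, adjusted p = 0.00122) and those of complexes II and III in 14 of 14 (-0.23, adjusted p = 0.00594). For each of these 4, adjusted p = 0.980 with an estimated correlation. None of these passed singly over all genes, and when adjusted over the list alone 2 genes of complex IV fell and none of the other complexes. With median-ratio scaling the medians were -0.18 for complex I (33 of 36 lower), -0.23 for complex IV, -0.18 for complex V, -0.10 for complexes II and III (13 of 14) and -0.31 for the ribosomal protein genes. With rescaling they were -0.15 (32 of 36), -0.20, -0.15 (13 of 15), -0.06 and -0.28, and all of these stayed called. Mitochondrially encoded mRNAs were higher in 10 of 13 (median 0.10, adjusted p = 0.000160; adjusted p = 0.980 with an estimated correlation), a call lost with median-ratio scaling (adjusted p = 0.0573). Mitochondrial ribosome genes were lower in 47 of 49 (-0.18, adjusted p = 0.0222; adjusted p = 0.980 with an estimated correlation), a call lost with median-ratio scaling (adjusted p = 0.0756) and with rescaling (adjusted p = 0.123). Of 21 small membrane protein genes all were lower (median -0.24, adjusted p = 0.00799; adjusted p = 0.980 with an estimated correlation), with 1 fall over all genes (Sln) and 2 when adjusted over the list alone. With median-ratio scaling 15 of the 21 were lower (-0.11, adjusted p = 0.0193), and with rescaling 14 (-0.07, adjusted p = 0.00781). Of 10 cardiomyocyte markers 9 were lower (-0.28, adjusted p = 0.0132; adjusted p = 0.980 with an estimated correlation), where Myl7 and Nppa fell over all genes and adjusted over the list alone. Red blood cell markers were higher in 8 of 8 (median 0.94, adjusted p = 6.76e-10; adjusted p = 0.980 with an estimated correlation), none of them singly on either count, and Hba-a2 reached 10179 TPM in Mut library 4 against 1237 to 2729 TPM in WT. No list of any tissue kept its call with an estimated correlation. Mut library 2 had the lowest values of Rps4x, Cox7a2, Atp5e and Ndufb2 and the highest mitochondrial share. The heart lists of extracellular matrix, acute phase, drug metabolism and sex-biased liver genes were called higher relative to other genes although their medians lay between -0.02 and -0.00, and had adjusted p = 0.980 with an estimated correlation. Their medians were between 0.08 and 0.16 with median-ratio scaling and rescaling.

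In liver, more genes rose than fell. Cyp2a4, a cytochrome P450 that is higher in female than in male mouse liver, rose from 0.673 ± 0.0790 TPM in WT to 28.5 ± 25.2 TPM in Mut (SD, n = 4; log2 fold change 3.72, SE 0.52, adjusted p = 0.0189). The Mut libraries ranged from 7.80 to 63.1 TPM. Related sequences, such as those of Cyp2a5, can share reads with it. Ttc39a (log2 fold change 2.07, adjusted p = 0.00333), Themis (2.33, adjusted p = 0.00840), the glutathione transferase Gsta1 (2.67), Cyp2a22 (2.66), Ly6d (2.30), Ifi27l2b (2.01), the iron-siderophore binding protein Lcn2 (1.96), Osbpl3 (1.67) and the cyclin Ccnd1 (1.65) were the other large rises. Papss1, which makes the sulfate donor of sulfation, rose from 2.59 ± 0.442 to 7.99 ± 0.888 TPM (log2 fold change 1.33, adjusted p = 0.00333). Igfbp2, an insulin-like growth factor binding protein, fell from 333 ± 25.2 to 118 ± 66.8 TPM (log2 fold change -1.65, adjusted p = 0.0313). The vasopressin receptor Avpr1a (-1.41), the leptin receptor Lepr (-1.32), Nup62cl (-1.26), the immunoglobulin gene Ighg2b (-1.24), Epop (-1.05), Zfas1 (-1.03) and Smad9 (-0.96) fell as well. Ide fell from 39.3 ± 1.25 to 26.4 ± 1.21 TPM (log2 fold change -0.56, adjusted p = 0.0114).

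**Figure D3:**
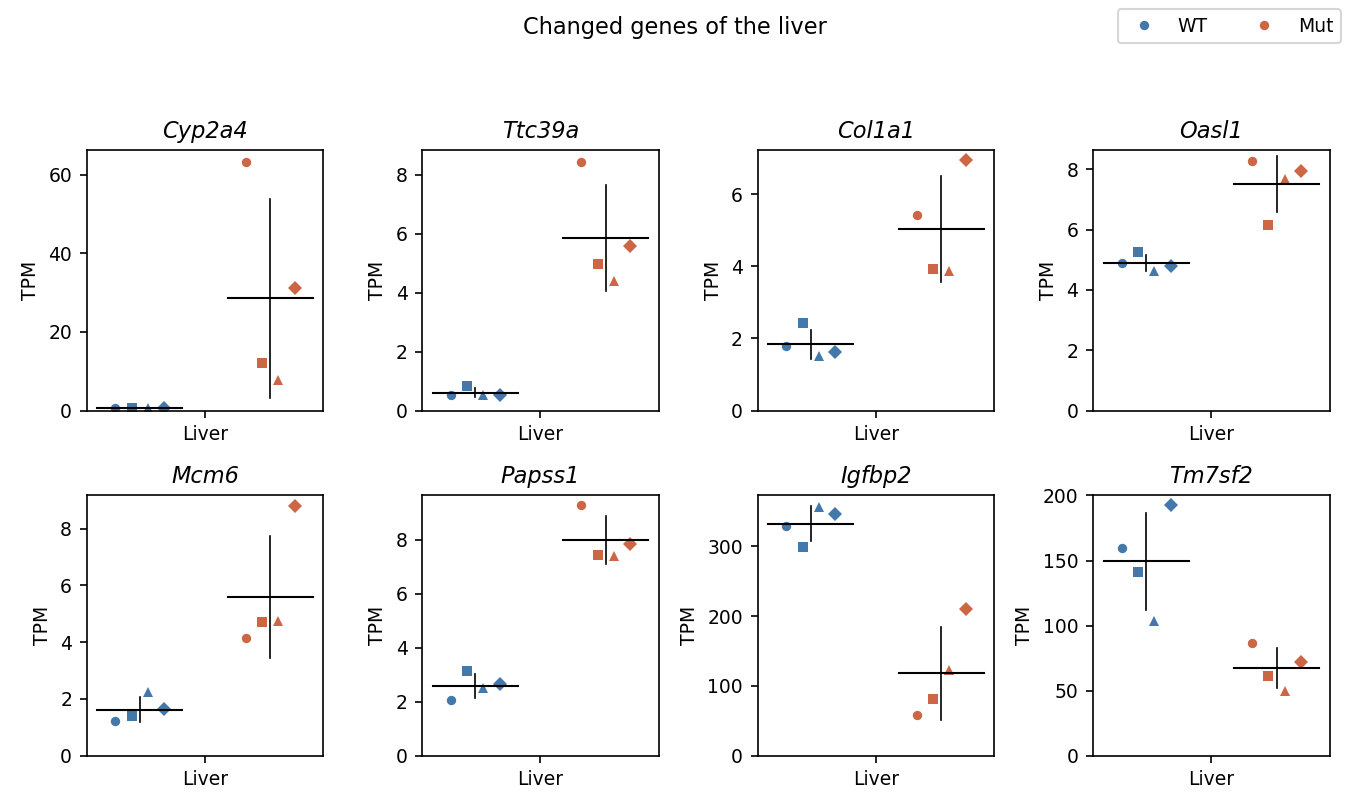
TPM of 8 liver genes per library, WT in blue and Mut in orange, with a marker shape per replicate number, the group mean as a line and the SD as a bar (n = 4). Cyp2a4, Ttc39a, Col1a1, Oasl1, Mcm6 and Papss1 are higher in Mut (Papss1 7.99 against 2.59 TPM), and Igfbp2 and Tm7sf2 lower (Tm7sf2 67.5 against 149.5 TPM).

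In total 499 of 11994 genes changed in liver, 453 up and 46 down, with 31 provisional names and a median absolute log2 fold change of 0.56. The groups did not overlap for 1966 genes (16.4%, where chance gives 2.86%). Median-ratio scaling gave 272 genes, 176 up and 96 down. Of the 38 named liver genes that passed, 29 lost their call without WT 3, 28 without Mut 1, 21 without WT 4, 19 without Mut 2, 13 without Mut 3, 10 without WT 1, 5 without Mut 4 and 4 without WT 2, while Papss1, Ide, Avpr1a, Themis and Ttc39a kept theirs under every alternative in which they were tested. The count of all liver genes was 22 without WT 3, 32 without Mut 1, 100 without Mut 2, 145 without WT 4, 254 without Mut 3, 288 without WT 1 and 293 without Mut 4. It was 35 with no filter on low values.

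Among the liver lists, interferon-stimulated genes were higher in 27 of 28 (median log2 fold change 0.46, adjusted p = 6.37e-05; adjusted p = 0.982 with an estimated correlation). Over all genes 5 rose, among them the oligoadenylate synthetase-like gene Oasl1 (4.90 ± 0.258 to 7.51 ± 0.934 TPM), Dhx58 and Usp18, and 18 rose when adjusted over the list alone. Extracellular matrix genes were higher in 18 of 18 (median 0.49, adjusted p = 3.54e-05; adjusted p = 0.982 with an estimated correlation), with 4 rises over all genes and 13 adjusted over the list alone. The collagens Col1a1 (1.83 ± 0.406 to 5.04 ± 1.46 TPM), Col1a2, Col3a1 and Col4a1 were those 4. Fibroblast markers were higher in 8 of 8 (0.37, adjusted p = 0.0154; adjusted p = 0.982 with an estimated correlation), with 3 rises over all genes and 3 adjusted over the list alone, all of them collagens of the matrix list. Of the antioxidant genes, targets of the transcription factor NRF2, 19 of 20 were higher (0.44, adjusted p = 0.00383; adjusted p = 0.982 with an estimated correlation). The 3 that rose were Gsta1, Srxn1 (log2 fold change 0.81) and Nqo1 (0.65), and 7 rose adjusted over the list alone. Peroxisome genes were higher in 22 of 24 (0.26, adjusted p = 0.00235; adjusted p = 0.982 with an estimated correlation), with Pex3 (0.53) and Hsd17b4 (0.47) as the 2 rises over all genes and 10 adjusted over the list alone. Cell cycle genes were higher in 11 of 12 (0.41, adjusted p = 0.0479; adjusted p = 0.982 with an estimated correlation), and Mcm2, Mcm3, Mcm5 and Mcm6, parts of the DNA replication helicase, were the 4 that rose, with 5 adjusted over the list alone. Macrophage markers were higher in 11 of 11 (0.88) without a call (adjusted p = 0.0730), and were called with median-ratio scaling (adjusted p = 0.0137) and with rescaling (0.0297), but not with an estimated correlation (adjusted p = 0.982). Their member Csf1r, chosen after its values were seen, read 21.8 TPM in Mut library 4, 7.69 to 10.6 TPM in the other Mut libraries and 3.21 to 12.4 TPM in WT.

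Other liver lists were lower. All 46 cytosolic ribosomal protein genes were lower (median log2 fold change -0.32, adjusted p = 4.46e-24; adjusted p = 0.982 with an estimated correlation), none singly on either count. Cholesterol synthesis genes were lower in 20 of 24 (median -0.45, adjusted p = 1.20e-07; adjusted p = 0.982 with an estimated correlation). Tm7sf2, a sterol reductase, fell from 149.5 ± 37.2 to 67.5 ± 15.5 TPM (log2 fold change -1.13, adjusted p = 0.0254) and was the 1 fall over all genes and adjusted over the list alone. Cyp51 (-1.11, adjusted p = 0.132) and Nsdhl (-1.02, adjusted p = 0.126) did not pass. Hepatocyte markers were lower in 10 of 10 (median -0.25, adjusted p = 0.000210; adjusted p = 0.982 with an estimated correlation), with none over all genes and 1 adjusted over the list alone, and Apoa1 read 11446 ± 1181 TPM in WT and 7040.2 ± 1685 TPM in Mut (adjusted p = 0.0561). Sex-biased liver genes, a list that mixes male-biased and female-biased genes, were lower in 11 of 15 (-0.16, adjusted p = 0.0331; adjusted p = 0.982 with an estimated correlation), a call lost with median-ratio scaling (adjusted p = 0.237), with no fall on either count and 1 rise adjusted over the list alone. Its member Cyp2b9, female-biased, read 44.9 ± 11.8 TPM in WT and 213 ± 115 TPM in Mut (adjusted p = 0.0584). Its male-biased member Hsd3b5 read 66.1 ± 37.1 TPM in WT and 14.4 ± 14.8 TPM in Mut (adjusted p = 0.0905).

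In skeletal muscle Ide was the 1 of 11771 genes that changed, and it fell from 90.1 ± 4.97 TPM in WT to 49.6 ± 4.91 TPM in Mut (SD, n = 4; log2 fold change -0.85, SE 0.08, adjusted p = 0.0204). The lipid droplet gene Plin4 was next (5.43 ± 1.15 to 1.97 ± 0.385 TPM, adjusted p = 0.0823). Btaf1, a regulator of the TATA-binding protein, read 5.30 ± 0.360 TPM in WT and 2.97 ± 0.526 TPM in Mut, and Rab4a 7.18 ± 0.954 and 12.9 ± 2.00 TPM (both adjusted p = 0.224). At an unadjusted p under 0.05 limma gave 745 higher and 168 lower genes, where independent genes would give 589 by chance, but 8 of the 35 splits of the libraries, the real one included, gave as many (highest other 2187). The groups did not overlap for 529 genes (4.49%, where chance gives 2.86%). The fall of Ide lost its call without WT 1, WT 2, WT 3, WT 4, Mut 3 or Mut 4 (adjusted p from 0.0695 to 0.163), at log2 fold changes of -0.81 to -0.88. Without Mut 1, 8 genes passed. With the replicate number as a block, none passed.

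Slow fibre genes of muscle were lower in 11 of 12 (median log2 fold change -1.09, adjusted p = 1.68e-10; adjusted p = 0.326 with an estimated correlation), none singly over all genes or adjusted over the list alone. The libraries of the Mut group differed among themselves. Tnni1, the slow skeletal troponin I, read 130.5 TPM in Mut library 1, within the WT range of 79.3 to 140.3 TPM, and 1.24 to 28.4 TPM in the other 3. Tnnc1 read 249 TPM in Mut library 1 and 32.3 to 84.1 TPM in the other 3. The lowest of these lay near the level of Tnnc1 in the liver libraries (30.0 to 36.7 TPM), so its fold change depends on that floor. The nuclear genes of respiratory complex I were lower in 36 of 36 (median -0.13, adjusted p = 2.13e-15), those of complexes II and III in 14 of 14 (-0.18, adjusted p = 1.68e-10), those of complex V in 13 of 15 (-0.16, adjusted p = 5.84e-09), those of complex IV in 12 of 13 (-0.16, adjusted p = 2.95e-08), and genes of the TCA cycle in 18 of 19 (-0.15, adjusted p = 1.68e-10). For each of these, adjusted p = 0.326 with an estimated correlation. Fatty acid oxidation genes were lower in 21 of 22 (-0.21, adjusted p = 4.30e-07; adjusted p = 0.640 with an estimated correlation). In all of these lists no member passed singly, over all genes or adjusted over the list alone. Pdha1 read 407 TPM in Mut library 1, within the WT range of 405 to 424 TPM, and 319.7 to 349.9 TPM in the other 3. Its log2 fold change in muscle went from -0.24 to -0.09 with a slow fibre score, added after the data were seen. Matrix and macrophage genes were higher. Extracellular matrix genes were higher in 26 of 26 (0.28, adjusted p = 1.68e-10; adjusted p = 0.326 with an estimated correlation), with 6 rises adjusted over the list alone, as Col5a2 (2.87 ± 0.344 to 4.38 ± 0.553 TPM). Macrophage markers were higher in 9 of 9 (0.45, adjusted p = 9.86e-09; adjusted p = 0.326 with an estimated correlation), with 7 adjusted over the list alone, as the receptor Csf1r (mean 3.48 TPM in WT, 5.56 TPM in Mut) and C1qa. Fibroblast markers were higher in 10 of 10 (0.33, adjusted p = 7.81e-07; adjusted p = 0.326 with an estimated correlation), with 7 adjusted over the list alone. None of these passed over all genes. White adipocyte markers were higher in 10 of 10 (0.32, adjusted p = 0.127) and red blood cell markers in 8 of 8 (0.59, adjusted p = 0.0958), neither of them called. Lep, the leptin gene of fat cells, was chosen after its values were seen. It read 28.5 and 18.3 TPM in Mut libraries 2 and 3, 5.67 and 6.88 TPM in Mut libraries 1 and 4 and 3.58 to 9.14 TPM in WT. Mut libraries 2 and 3 also had the lowest Tnni1 (5.55 and 1.24 TPM) and the highest Dpt (56.2 and 53.6 TPM).

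**Figure D4:**
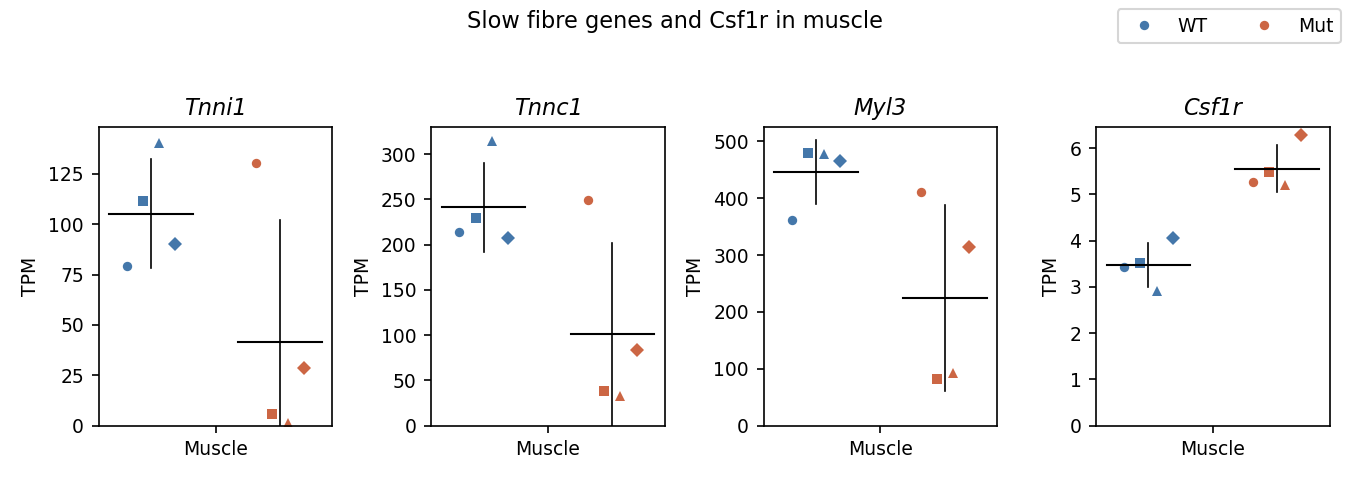
TPM of the slow fibre genes Tnni1, Tnnc1 and Myl3 and of the macrophage receptor gene Csf1r per muscle library, WT in blue and Mut in orange, with a marker shape per replicate number, the group mean as a line and the SD as a bar (n = 4; bars end at 0). Tnni1 is at 130.5 TPM in Mut library 1 and at 1.24 to 28.4 TPM in the other 3 Mut libraries.

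In BAT no gene passed over the 12150 tested, while matrix, macrophage and blood cell genes were higher and genes of fat oxidation lower as groups. No list of BAT kept its call with an estimated correlation (adjusted p of 0.355 or more). Entpd4, a nucleoside diphosphatase of the Golgi, came nearest (101 ± 22.1 TPM in WT and 38.4 ± 4.84 TPM in Mut; SD, n = 4; log2 fold change -1.35, adjusted p = 0.0609). Gpd2, the mitochondrial glycerol phosphate dehydrogenase, read 157 ± 4.14 and 104 ± 10.9 TPM, and the eosinophil chemokine Ccl11 18.4 ± 1.61 and 28.0 ± 2.11 TPM (both adjusted p = 0.106). At an unadjusted p under 0.05 limma gave 2369 genes, 2084 higher and 285 lower, where independent genes would give 608 by chance and the highest other split of the libraries gave 2299. The groups did not overlap for 1143 genes (9.41%, where chance gives 2.86%). The count was 819 without WT 3 and 1 without WT 4. It was 648 with array weights, 848 with 1 fit over all libraries, 4 with no filter and 1 with a filter at 5 TPM or an adjusted p under 0.1. WT libraries 1 and 2 lay apart from the other 6 on the first principal component (34.5 and 29.0, others 0.850 or lower), and without both of them no gene passed and 18 lists were called, 17 of them among the 26 called with all libraries.

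Extracellular matrix genes of BAT were higher in 27 of 28 (median log2 fold change 0.72, adjusted p = 9.97e-10; adjusted p = 0.561 with an estimated correlation), and 24 rose when adjusted over the list alone, as Col3a1 (64.5 ± 28.4 TPM in WT, 169 ± 60.8 TPM in Mut). Fibroblast markers were higher in 10 of 10 (0.83, adjusted p = 3.84e-05; 9 adjusted over the list alone), macrophage markers in 10 of 10 (1.20, adjusted p = 0.000123; 8 adjusted over the list alone) and red blood cell markers in 7 of 8 (0.78, adjusted p = 0.000133; 7 adjusted over the list alone). For each of these 3, adjusted p = 0.561 with an estimated correlation. The macrophage gene C1qa read 23.6 ± 13.1 TPM in WT and 50.8 ± 7.19 TPM in Mut, with 11.3 and 14.9 TPM in WT 1 and WT 2 and 39.8 and 28.5 TPM in WT 3 and WT 4. Its log2 fold change was 1.23 with all libraries and 0.57 without WT 1 and WT 2, and its adjusted p ranged from 0.0171 to 0.301 over the alternatives. Without these 2 libraries the medians were 0.44 for macrophage markers, 0.34 for extracellular matrix, 0.63 for fibroblast markers, 0.56 for red blood cell markers and 0.28 for the cell cycle, all still called, and 0.32 for immediate early genes, no longer called (adjusted p = 0.153). The globin gene Hbb-bt read 170.1 ± 41.1 TPM in WT and 322 ± 74.2 TPM in Mut. Interferon-stimulated genes were higher in 24 of 25 (0.34, adjusted p = 3.08e-05; 6 adjusted over the list alone; adjusted p = 0.561 with an estimated correlation). Immediate early genes were higher in 23 of 24 (0.76, adjusted p = 0.000123; 8 adjusted over the list alone), cell cycle genes in 14 of 14 (0.56, adjusted p = 0.000204; 11 adjusted over the list alone) and cytosolic ribosomal protein genes in 46 of 46 (0.22, adjusted p = 2.32e-07; none adjusted over the list alone), with adjusted p = 0.603 with an estimated correlation for each. Fast muscle fibre genes were higher in 16 of 16 (0.46, adjusted p = 0.0118; none adjusted over the list alone; adjusted p = 0.731 with an estimated correlation), as Acta1 (278 ± 15.6 TPM in WT, 436 ± 144 TPM in Mut), which in Mut 4 (253 TPM) lay below every WT library (260.1 to 292 TPM). Acta1 read 273 ± 10.3 TPM in WT liver and 307 ± 66.4 TPM in WT heart, so its WT level in BAT lay near that of other tissues without skeletal muscle. Skeletal muscle fibre markers were higher in 10 of 10 (0.49, adjusted p = 0.0329; adjusted p = 0.731 with an estimated correlation), a call lost with rescaling (adjusted p = 0.0535). No member of these lists passed over all genes.

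Metabolic lists were among the lower ones of BAT. Genes of the TCA cycle were lower in 15 of 19 (median -0.17, adjusted p = 2.63e-10; adjusted p = 0.561 with an estimated correlation), with 1 fall adjusted over the list alone, Pdha1 (602 ± 28.4 TPM in WT, 453 ± 31.5 TPM in Mut). Genes of fatty acid oxidation were lower in 20 of 22 (-0.11, adjusted p = 7.43e-10; 2 falls adjusted over the list alone), and those of fatty acid and triglyceride synthesis in 15 of 23 (-0.06, adjusted p = 4.15e-05; 3 falls adjusted over the list alone). For both, adjusted p = 0.561 with an estimated correlation. Among the latter, Acaca read 111 ± 26.5 and 59.4 ± 7.96 TPM and Elovl6 54.8 ± 15.3 and 29.5 ± 1.13 TPM. Thermogenesis genes were lower in 20 of 27 (-0.14, adjusted p = 1.35e-08; 4 falls adjusted over the list alone; adjusted p = 0.355 with an estimated correlation), as the lipid-sensing receptor gene Ppara (47.6 ± 8.24 TPM in WT, 27.8 ± 3.17 TPM in Mut, adjusted p = 0.106). The lists of peroxisome, glycolysis, circadian clock and PPAR target genes were called lower relative to other genes although their medians lay between 0.01 and 0.02, with adjusted p = 0.561 with an estimated correlation. Their medians were negative with median-ratio scaling and rescaling. Without WT 1 and WT 2 the calls of peroxisome (adjusted p = 0.536), PPAR target (0.465) and glycolysis genes (0.0661) were lost, and the clock genes kept theirs (0.0336). The nuclear genes of complex I (median -0.02, adjusted p = 0.000392) and of complexes II and III (-0.05, 0.000109) also lost their calls without them (0.622 and 0.342). Complex I genes were then higher in 26 and lower in 10. Heat shock genes, not called with all libraries (-0.02, 0.0673), were then called lower (-0.50, 3.40e-05). Mitochondrial chaperones and proteases were lower in 10 of 12 (-0.06, adjusted p = 0.00192; adjusted p = 0.561 with an estimated correlation). None of the members of these lists passed over all genes.

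The comparison over tissues asked whether the genotype difference varied between them. Of 10109 genes tested, 593 had an effect that differed between tissues by the interaction F test. Myl7 (adjusted p = 1.98e-07), Myl4 (2.78e-07) and Nppa (0.000356) fell in heart, and Papss1 (1.19e-06) and Fam241b (0.000356) rose in liver. Between pairs of tissues, 711 genes differed between BAT and heart, 668 between heart and liver, 310 between BAT and liver, 55 between liver and muscle, 3 between heart and muscle, and none between BAT and muscle (smallest adjusted p = 0.180). The effect on Smim30 differed between BAT and heart (adjusted p = 0.0351), while its interaction test over the 4 tissues did not pass (adjusted p = 0.0701). Averaged over tissues, with the libraries taken as independent, 412 genes changed, 345 up and 67 down. With each replicate number of a genotype taken as 1 animal in all tissues, 199 changed. In the fit with independent libraries Rab4a had the smallest p (average log2 fold change 0.55, adjusted p = 2.22e-05), and it was higher in all 4 tissues. Median-ratio scaling gave 1011 genes, 605 up and 406 down. Leaving out 1 library gave 254 to 1030 genes for the interaction and 192 to 798 for the average, where the extremes came without BAT WT 1 (192), BAT WT 3 (798 and 1030) and liver WT 3 (254).

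There were 2 genes called in the same direction in more than 1 tissue, Ide and Gm47283. Ide (chromosome 19, 37268743 to 37337852) fell in heart, liver and muscle, and its effect differed between tissues (adjusted p = 0.00478). In BAT it read 30.3 ± 10.1 TPM in WT and 39.1 ± 10.7 TPM in Mut (log2 fold change 0.37, adjusted p = 0.485), and the difference from the other tissues passed against heart (adjusted p = 0.00321) and liver (0.0316) but not muscle (0.180). Each pair of tissues was adjusted over its own genes, so these adjusted p do not rank the pairs. The fall of Ide was larger in muscle than in liver. The effects of heart, liver and muscle on Ide were not shown to differ from each other (adjusted p = 0.228 to 0.765). Gm47283, a provisional name at the end of chromosome Y (90784738 to 90816464), fell in heart (8.42 ± 2.20 to 2.21 ± 0.529 TPM, log2 fold change -1.54) and liver (12.7 ± 3.77 to 3.30 ± 1.46 TPM, log2 fold change -1.70). It was lower on average over tissues, with the libraries taken as independent (adjusted p = 0.000195). Heart and liver shared 2 falls where independent calls would share 0.0311 (one-sided Fisher's exact p = 0.000416, adjusted p = 0.00166). Ide was the 1 gene that muscle shared with heart or liver. Without liver WT 3 or liver Mut 1 the number of shared genes was 1, and without BAT WT 3 it was 49. Across genes, which are not independent replicates, the fold changes of the 6 pairs of tissues had Pearson's r from -0.05 (BAT and heart) to 0.28 (heart and liver).

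**Figure D5:**
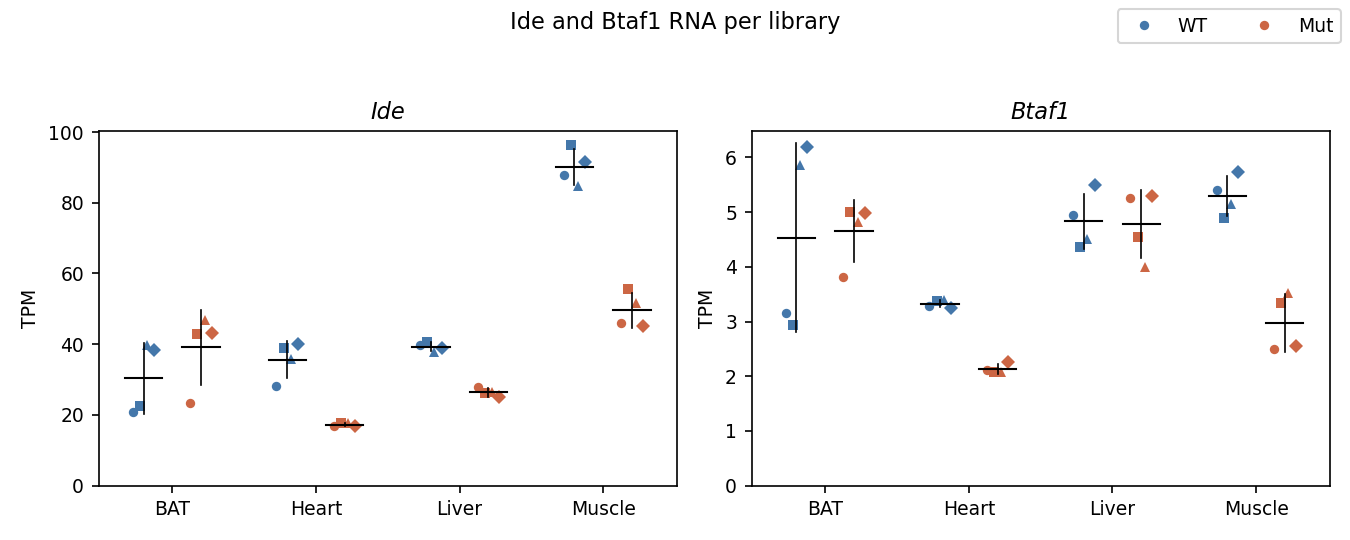
TPM of Ide and Btaf1 per library in the 4 tissues, WT in blue and Mut in orange, with a marker shape per replicate number, the group mean as a line and the SD as a bar (n = 4). Ide is lower in Mut in heart, liver and muscle (49.6 against 90.1 TPM in muscle) and overlaps in BAT, and Btaf1 is lower in heart and muscle (2.97 against 5.30 TPM in muscle), where it did not pass.

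The genes beside Smim30 were tested as well. Tmem106b, Tmem168 and Bmt2 on one side, and 1110019D14Rik, Ppp1r3a and Foxp2 on the other, did not pass in any tissue where they were tested. The smallest adjusted p was 0.0894, for 1110019D14Rik in liver (1.66 ± 0.155 TPM in WT, 2.30 ± 0.176 TPM in Mut).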

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

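The tests on atrial markers, on Ide in BAT against the other tissues, on transcripts seen at a low level in other tissues (carry-over and low expression) and on other splits of the libraries were chosen after the results were seen, as were the alternatives with an atrial score and without BAT WT 1 and WT 2.

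In some groups of 4 libraries, 1 library lay far from the other 3 for a named gene, by the ratio of its gap to the whole range (Dixon's ratio). This held for 19 of 316 groups, where chance gives 15.8, about 1 in 20. Heart Mut library 2 stood apart for Rps4x (0.855), Cox7a2 (0.961), Atp5e (0.932) and Ndufb2 (0.929), all lower than the other 3, and for mt-Atp8 (0.849), which was higher. Heart Mut library 3 stood apart, higher, for Sln (0.872), Myl7 (0.850) and Myl4 (0.958), with 20.6 TPM of Myl7 against 2.64 to 3.76 TPM in the others. Heart WT library 4 was higher for Alas2 (0.840). Liver WT library 2 was higher for Ttc39a (0.913), Ccnd1 (0.857), Mcm5 (0.966) and Fam241b (0.916). Liver Mut library 1 was higher for Ifi27l2b (0.881) and liver Mut library 4 for Mcm6 (0.834). Muscle WT library 1 was lower for Myl3 (0.886) and muscle Mut library 1 higher for Cd68 (0.942). BAT Mut library 2 was lower for Ppargc1b (0.851), and BAT Mut library 1 was lower for Ide (0.868; 23.3 TPM against 42.8 to 47.0 TPM in the others).

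The genotype effect differed between tissues for 593 genes. It differed between BAT and heart for 711 genes, between heart and liver for 668, between BAT and liver for 310, between liver and muscle for 55 and between heart and muscle for 3. The adjusted p of the interaction was 1.98e-07 for Myl7, 2.78e-07 for Myl4, 1.19e-06 for Papss1, 0.000356 for Fam241b and for Nppa, and 0.00478 for Ide. The effect on Smim30 differed between BAT and heart with adjusted p = 0.0351. Chance was argued against for the number of 593 genes, since 1 of 100 draws of the labels, the real one included, gave as many, and the highest of the others was 194. With a replicate number of a genotype taken as 1 animal in all tissues, 1 of 35 splits gave as many, and the highest other was 10. Among transcripts that matched no gene, 1 of 430 tested in BAT rose and 1 of 635 tested in liver rose, which the comparisons of genes do not use.

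The fall of Myl7, Myl4, Sln, Nppa and other atrial genes was found in the heart libraries labelled Mut. A shift of the TPM scale by a few abundant transcripts was argued against, since the median log2 fold change of 7 atrial sarcomere and peptide genes was -4.37 after rescaling without mitochondrial and the 10 most abundant genes. Among the WT libraries, WT 3 was the lowest for all 7 of these genes. Myl7 read 96.8 TPM there against 371 to 626 TPM in the other WT libraries, and Nppa 143 against 763 to 2049 TPM. These genes thus varied together within 1 genotype as well. Less atrial tissue in the Mut samples may contribute, on weak evidence: a list of other atrial markers, written after the heart calls were seen, without the called genes and with Bmp10 (-1.55) and Stard10 (-1.06) taken off once their values were seen, had a median of -0.38 over 11 measured genes, 10 of them lower, against -0.25 over 9 ventricle markers, 7 of them lower. After rescaling the medians were -0.33 and -0.08, and the atrial markers ranged from -2.39 to 0.14 before it. With the mean of that list as a covariate Myl7 went from -5.78 (SE 0.64) to -3.73 (SE 0.63) and its call ended (adjusted p = 0.517), with fewer degrees of freedom and a score that moves with genotype, so a difference in dissection and a genotype effect on atrial genes both stay open.

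Ide was lower in the libraries labelled Mut of heart, liver and muscle but not of BAT. Whether a variant carried by the line acts alike in every tissue was not decided. The BAT effect exceeded the mean of the other 3 by 1.17 on the log2 scale (SE 0.33, 98.75% interval 0.01 to 2.32, for 1 tissue picked of 4). Without BAT WT 1 and WT 2 this was 0.76 (interval -0.38 to 1.89), so the difference rests on those 2 libraries. The contrast takes each label as 1 level, but Ide in BAT split across the labels. It read 20.8, 22.5 and 23.3 TPM in WT 1, WT 2 and Mut 1 against 38.2 to 47.0 TPM in the others. BAT WT libraries 1 and 2, with 20.8 and 22.5 TPM of Ide, could be Mut libraries, but on 194 genes changed over the other tissues the higher of their scores was -0.20, below the lowest BAT Mut library (0.01), although WT 3 and WT 4 (0.09 and 0.06) scored above 3 of the 4 Mut libraries, so the score separates the genotypes of BAT poorly. Of its neighbours on chromosome 19, chosen after their values were seen, Btaf1 had a Mut to WT ratio of 0.641 in heart, 0.561 in muscle, 0.989 in liver and 1.03 in BAT. Within BAT, Btaf1 was low in the libraries where Ide was low. It read 3.16, 2.93 and 3.82 TPM in WT 1, WT 2 and Mut 1 against 4.81 to 6.18 TPM in the others. The other neighbours included Cpeb3 at 1.28 and Tnks2 at 1.14 in liver, Kif11 at 1.84 in BAT (under 1 TPM) and March5 between 0.946 and 1.04. A genotype effect that differs between tissues and a variant near Ide that acts in some tissues stay open and were not tested. Smim30 lies on chromosome 6, so a variant near Ide would not be linked to it. A variant that acts in every tissue stays open as well.

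Transcripts typical of 1 tissue were seen at a low level in the others. Low expression in the receiving tissue as the whole cause was argued against for liver and muscle genes: over all nuclear protein-coding genes of 500 TPM or more in the source, the lowest level elsewhere was 0.901% of the source for liver and 1.12% for muscle, and 90 to 98 of 205 liver genes and 17 to 27 of 128 muscle genes lay within 1.5 times the lowest, a shared floor. For heart genes (lowest 1.25%) and BAT genes (1.56%) fewer than 10 genes lay that near in 1 or more receiving tissues, and low expression stays open for them, as it does for single genes above the floor. A possible explanation of the floor is carry-over between libraries, since the 10 genes most specific to the source had a median level of 1.56% over the 12 pairs of tissues (0.973% to 4.08%), but 1 pair, the BAT genes in heart, spread by an SD of log2 ratios of 1.14, beyond the bound of the test, and genes picked by their ratio spread less, so it stays open. Levels of such genes outside their own tissue, as Nppa at 8.73 ± 0.938 TPM in WT liver (SD, n = 4), are given with this limit.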

How the results depend on the processing

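The alternatives with an atrial score, with a slow fibre score and without BAT WT 1 and WT 2 were chosen after the data were seen, and the cause of each difference was not tested except where fewer genes or libraries were tested. TPM hold no depth, so counting error is not covered. Numbers of changed genes moved most. With no filter they were 4 in BAT, 0 in heart, 35 in liver, 6 in muscle, 680 on average and 1 shared, with 22 liver lists. At a mean of 5 TPM they were 1 in BAT, 10 in heart, 355 for the interaction and 129 on average. Median-ratio scaling gave 11 in heart, 272 in liver (218 of the 499) and 1011 on average, and rescaling without mitochondrial and abundant genes 1355 on average. Array weights gave 648 in BAT, 44 in heart, 1901 for the interaction, 1939 on average and 40 shared. The replicate block gave 9 in heart, 126 in liver and 0 in muscle. The numbers do not pair WT with Mut, since residuals of equal numbers had r between -0.25 and 0.14 across genes. Across tissues, libraries of 1 genotype with equal numbers had a mean r of 0.0648 (18 of 48 over 0.1). The mean of -0.0214 for other numbers is no separate comparison, since values were centred within each group of 4. With each number of a genotype as 1 animal there were 199 genes on average, all among the 412, and 772 for the interaction. With 1 fit over all libraries there were 848 in BAT, 166 in heart, 1902 in liver and 7 in muscle. At an adjusted p under 0.1 there were 1 in BAT, 1453 in liver and 2 in muscle. Genes above 1 TPM in any tissue gave 771 on average. With an estimated correlation 0 lists were called in each tissue. The atrial score gave 0 genes in heart and the slow fibre score 2 in muscle.

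Smim30 in heart passed with array weights (-0.50) and with 1 fit (-0.55). The Smim30 BAT difference, near 0, turned to -0.0354 with median-ratio scaling, -0.0147 with rescaling, -0.12 without BAT WT 1 and WT 2, -0.0374 without WT 1 and -0.00228 without Mut 4. Ide in BAT turned to -0.0450 without WT 1 and WT 2, and Myl2 in Muscle to 0.0370 with the slow fibre score.

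Leaving out 1 library at a time gave changed genes of 0 to 819 in BAT, 7 to 20 in heart, 22 to 390 in liver and 0 to 8 in muscle, 254 to 1030 for the interaction, 192 to 798 on average and 1 to 49 shared. Lists numbered 22 to 29 in BAT, 16 to 18 in heart, 13 to 17 in liver and 18 to 29 in muscle. Smim30 ranged from -0.04 to 0.11 in BAT, -0.62 to -0.43 in heart, -0.23 to -0.05 in liver and -0.42 to -0.36 in muscle.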

Other observations

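The tests of other splits of the libraries and the alternative with a slow fibre score were chosen after the results were seen.

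Some lists fixed before the data were examined have not been described yet. In muscle, genes of the endoplasmic reticulum unfolded protein response were higher in 19 of 21 (median log2 fold change 0.10, camera adjusted p = 0.0133; adjusted p = 0.558 with an estimated correlation), as the chaperone gene Pdia4 (5.85 ± 0.185 TPM in WT, 7.51 ± 0.673 TPM in Mut; SD, n = 4). Genes of ketone body metabolism were lower in 5 of 5 (-0.26, adjusted p = 0.00453; adjusted p = 0.326 with an estimated correlation), as Oxct1, which activates ketone bodies (173 ± 21.7 TPM in WT, 124 ± 28.9 TPM in Mut). Oxct1 read 164 TPM in Mut library 1, within the WT range of 143 to 192 TPM, as the slow fibre genes Tnni1 and Tnnc1 did, and its log2 fold change went from -0.50 to -0.17 with the slow fibre score. No member of these lists passed over all genes or adjusted over the list alone. Interferon-stimulated genes of muscle were higher in 16 of 19 (0.14, adjusted p = 0.0252; adjusted p = 0.326 with an estimated correlation), and those of heart in 16 of 24 (0.09, adjusted p = 5.03e-06; adjusted p = 0.980 with an estimated correlation), with none passing on either count. Brown adipocyte markers of BAT were not called (6 of 10 lower, adjusted p = 0.122), nor with median-ratio scaling (9 of 10 lower, adjusted p = 0.0754), but were called lower with rescaling (7 of 8, adjusted p = 0.0190).

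The provisional gene AC102496.1 on chromosome 18 was singled out after its values were seen. Mut library 1 lay within the WT range in each tissue, at 8.57 TPM in BAT, 3.99 in heart, 31.6 in liver and 4.07 in muscle. The other 3 Mut libraries lay below the WT libraries, at 2.62 to 4.80 TPM in BAT against 6.92 to 12.5 TPM, 0.375 to 1.16 TPM in heart against 3.37 to 4.35 TPM, 10.2 TPM or less in liver against 28.6 to 42.0 TPM, and 0.694 to 1.87 TPM in muscle against 3.50 to 4.39 TPM. Muscle Mut library 1 was also the 1 Mut library with the slow fibre genes Tnni1, Tnnc1, Tpm3, Myl3 and Myl2 in the WT range. For Ide, Mut library 1 lay below the WT range with the other Mut libraries in 3 tissues. It read 46.0 TPM in muscle (WT 84.6 to 96.2), 16.8 in heart (WT 28.1 to 39.9) and 27.9 in liver (WT 37.8 to 40.7). In BAT its 23.3 TPM lay within the WT range (20.8 to 39.8).

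Other splits of the 8 libraries of a tissue into 4 and 4 were counted, 35 per tissue with the real one. The share of 1 of 35 is the smallest possible, and shares were not adjusted over the numbers compared. Splits cannot tell the genotype from another difference that goes with the labels. Chance was argued against for the 18 changed genes of heart (1 of 35 splits reached this number, highest other 2) and the 499 of liver (1 of 35, highest other 2). It cannot be excluded for the 1 gene of muscle (6 of 35, highest other 9). The 0 genes of BAT are reached by any split (35 of 35, highest other 1), so this number tests nothing. For genes with an unadjusted p under 0.05, chance was argued against for the 3102 of liver (1 of 35, highest other 1952). It was argued against only narrowly for the 2369 of BAT (1 of 35, the smallest share the design allows), since another split gave 2299. It cannot be excluded for the 1399 of heart (3 of 35, highest other 2696) or the 913 of muscle (8 of 35, highest other 2187). Nor can it be excluded for the number of called lists, which was 26 in BAT (6 of 35 splits, highest other 28), 17 in heart (2 of 35, highest other 17), 13 in liver (21 of 35, highest other 33) and 19 in muscle (15 of 35, highest other 27). The median over the other splits was 18 called lists in BAT, 12 in heart, 13 in liver and 17 in muscle. Over tissues, with 100 draws, the number of 2 shared genes was reached in 1 of 100 (highest other 1). Other splits called a median of 0 genes in each tissue, so the draws could hardly give shared genes. They therefore do not test the sharing itself. By the share, chance was argued against for the 412 genes changed on average (2 of 100). But 1 draw gave 955 genes, more than the real number, and what set it apart was not tested. These draws mix the labels of each tissue apart from the others. With a replicate number of a genotype taken as 1 animal in all tissues, chance was argued against too for the average (1 of 35 splits, highest other 5). The number of shared genes was reached in 1 of 35 splits (highest other 0), with the same limit as for the draws.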
